A study of Arabidopsis thaliana with 6 samples.

How the data were processed

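RNA was extracted from whole seedlings with a column kit and sequenced as libraries made with an RNA library kit that does not name a strand, per the labels' protocols. Plants were grown at 22 °C with 16 h of light and 8 h of dark and taken at an age of 10 days, per the labels' protocols. The submitters' processing notes name fastp 0.20.1, HISAT2 2.1.10, DESeq2 1.26.0 and the TAIR10 genome build. The tool that counted reads per gene, its strand setting and the annotation release are not given in the sources used here. The authors deposited 1 table of TPM values for 27655 genes in the 6 libraries, and each library's values add to 1000000. Its columns were matched to samples by their names.

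TPM keeps no depth by itself, so the lengths behind the values were looked for. With the full span of each gene in the reference annotation (introns included) as its length, the deposited TPM of 22980 of 22985 expressed genes (99.98%) came out as whole reads in all 6 libraries, within a tolerance of 0.02 reads. With exon length, 0.0524% of 19089 genes with introns did. The values thus follow a gene-span length, which lowers the TPM of genes with long introns. The choice of length also enters the scaling of each library. With TPM recomputed from exon lengths 2458 genes changed instead of 2285, and of the 2264 of these 2285 tested there 2210 were called again. The recovered reads gave 14364242, 13792031 and 13793387 for wild type replicates 1 to 3 and 14038569, 14498093 and 13898956 for the h3.3ko;HTR5 replicates. At these depths 3 reads, used as the floor for a gene listed at 0, correspond to 0.25 TPM for AT2G10940. Floors cover counting error only.

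Gene identifiers were matched to the TAIR10.1 reference annotation (27445 of 27655, 99.2%), whose coordinates are printed, and the 5 nuclear chromosomes are those of TAIR10. Mitochondrial identifiers beginning with ATMG had no match. The table lists 4516 genes at 0 in all libraries. Of the changed genes 532 (23.3%) overlap another annotated gene, against 30.5% of those tested, and since the strand setting is not given, reads of overlapping genes cannot be told apart. Among the genes chosen by the rule given further on, 21 overlap another gene, including AT2G05915, CHS, TT19, WRKY40, FLC, SPL3, PAP17, TSO2, MCM7, LNK2 and EF1A. Exon windows of 50 bases were looked up on both strands of the genome, and 5 of the chosen genes share over 10% of theirs with another place: PRR9, SNC1, RBCS2B, RBCS3B and LHCB1.2. ATMG00665, ATMG01370 and ATMG00690 are among the chosen genes but have no coordinates, so neither their windows nor their read numbers could be checked.

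The test used limma 3.58.1 in R 4.3.3 on log2(TPM + 1), for the 19013 genes with a mean TPM of at least 1 over the 6 libraries, with lmFit and eBayes with a trend in the variance prior, and no replicate block. It was two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Log2 fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. Means ± SD are of the deposited TPM over 3 libraries per group. This test was chosen for TPM values before the data were examined. Reads were recovered only later, so a model of reads (voom) is given as an alternative. Replicates of a group differed by more than counting noise (chi-square per degree of freedom of 2.13 to 3.91), which separate preparations of the same RNA would show as well, so technical repeats are not ruled out. On simulated counts with 200 genes changed, of which 67, 66 and 65 by a log2 of 0.5, 1 and 2 were among the 18911 tested, the same test recovered 35.8% of genes changed by a log2 of 0.5, 87.9% of those changed by 1 and 100% of those changed by 2. It made 166 calls there, of which 19 were false, above the nominal 5%, and voom made 163 with 8 false. The simulation gave every gene the same spread between replicates, a coefficient of variation of 0.1 beyond counting noise. That spread was set and not estimated from these libraries, so these rates need not hold for the data.

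There were 25 gene lists with 299 genes, fixed before the data were examined: H3.3 genes, H3.1 genes, H3 chaperones, H3K36 methylation, flowering time, floral and meristem identity, abscisic acid and drought, cold, heat shock, salicylic acid defence, jasmonate and ethylene defence, rapid stress and touch, circadian clock, photosynthesis, root markers, seed maturation, cell division, DNA damage, phosphate starvation, iron deficiency, flavonoid and anthocyanin, glucosinolate, senescence, silenced loci and reference genes. The 23 lists with at least 3 tested members were compared with all other genes by camera with a preset correlation of 0.01, adjusted over the 23 lists, and again with an estimated correlation, with which no list passed. As an alternative, fry tested each list against no change, which is another question than that of camera. The genes named were chosen by a rule fixed before the data were examined: the H3.3 genes, the 10 largest log2 fold changes in each direction among changed genes whose groups do not overlap, up to 4 members of the smallest p per list, and the reference genes, 113 genes in all. A further 20 genes were named after their values were seen. The alternatives were other pseudocounts, filters, scalings and limma options, a replicate block, each library left out, and 3 chosen after the data were seen: voom on the recovered reads, TPM recomputed with exon lengths, and removal of each library's trend with exon length. Figures were drawn with matplotlib.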

Results

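RNA-seq was carried out on Arabidopsis thaliana seedlings 10 days old, with 3 libraries of wild type plants of the Col background and 3 libraries of a line labelled h3.3ko;HTR5. H3.3 is the histone H3 variant that is loaded onto chromatin outside DNA replication, and HTR4, HTR5 and HTR8 are the genes that encode it. The line's name joins a knockout of H3.3 with HTR5, and how the line was built is not given in the sources used here. The study's title concerns an amino acid particular to plant H3.3, methylation at lysine 36 of histone H3 (H3K36), development and stress responses. The comparison asks which transcripts differ in h3.3ko;HTR5. The values were TPM, a read number scaled for gene length and library total. The reads recovered from them came to 13792031 to 14498093 per library, with 18812 to 19104 genes at a TPM of at least 1. The labels do not say that libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

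HTR8 was nearly absent from h3.3ko;HTR5, while HTR4 and HTR5 were reduced and still among the well expressed genes. HTR8 (AT5G10980, chromosome 5, 3472405 to 3473570, TAIR10.1) stood at 315, 324 and 289 TPM in wild type replicates 1 to 3. In the h3.3ko;HTR5 replicates it stood at 3.19, 5.2 and 5.03 TPM, 69.1-fold lower on the means (log2 fold change -5.84 ± 0.13 SE, limma adjusted p = 4.08e-09). HTR4 (AT4G40030, chromosome 4, 18555532 to 18557106) fell from 331, 309 and 323 TPM to 148, 149 and 155 TPM (log2 fold change -1.08 ± 0.04 SE, limma adjusted p = 5.06e-07). HTR5 (AT4G40040, chromosome 4, 18557149 to 18558945) fell from 423, 403 and 411 TPM to 290, 298 and 296 TPM (log2 fold change -0.48 ± 0.04 SE, limma adjusted p = 7.70e-05). All 3 H3.3 genes fell, also when adjusted over the list alone (0 higher, 3 lower). As a list they were lower than other genes (camera adjusted p = 7.06e-06, and adjusted p = 0.364 with an estimated correlation). The line's name gives H3.3 as knocked out, so this list result is no independent finding. Transcripts of an introduced HTR5 copy and of the resident gene cannot be told apart in these values.

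**Figure D1:**
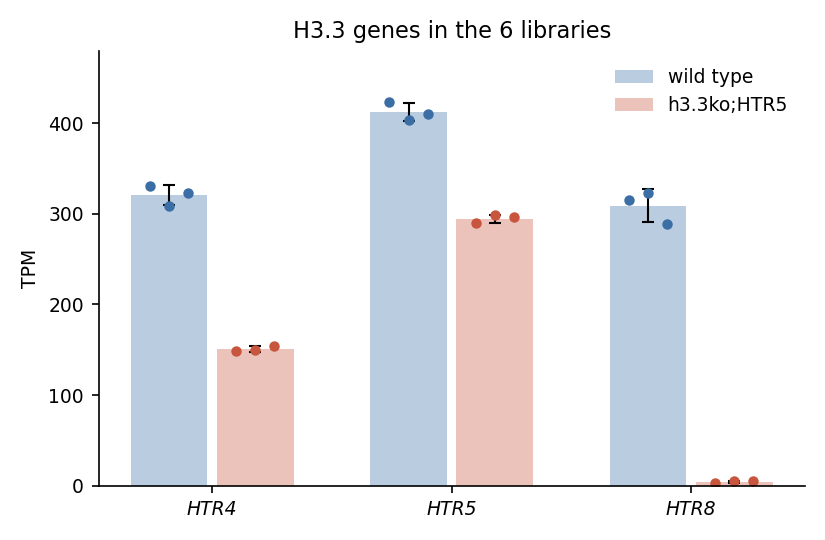
TPM of the H3.3 genes HTR4, HTR5 and HTR8 in wild type (blue) and h3.3ko;HTR5 (red), with 1 point per library, bars at the mean and error bars of 1 SD (n = 3). HTR8 lies between 3.19 and 5.2 TPM in the h3.3ko;HTR5 libraries, and HTR4 and HTR5 are lower than in wild type by less.

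Among 19013 tested genes, 2285 (12%) differed between the genotypes. Of these, 703 were higher and 1582 lower in h3.3ko;HTR5 (limma, two-sided, Benjamini-Hochberg adjusted p under 0.05). Most differences were modest, with a median absolute log2 fold change of 0.43 among these genes. By contrast 194 changed at least 2-fold by that estimate (37 higher, 157 lower). The size of the excess of lower genes among all changed genes depended on the scaling, but lower genes stayed the majority. The median log2 fold change of all tested genes was -0.034 as deposited and 0.014 after quantile normalization. That shift is small against a 2-fold change, and the 2-fold counts were not repeated with other scalings. Of the changed genes 30.8% were higher with the TPM as deposited, 46.4% after quantile normalization, 42.8% after median-of-ratios scaling and 44.5% once each library's trend with exon length was removed. The count fell to 1464 without wild type replicate 2 (416 higher, 1048 lower) and to 1289 without h3.3ko;HTR5 replicate 3 (354 higher, 935 lower). The higher genes alone fell to 453 without wild type replicate 3 and 459 without h3.3ko;HTR5 replicate 2.

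The largest log2 decrease was that of AT2G10940, a member of the lipid-transfer and seed storage protein superfamily (chromosome 2, 4310321 to 4312162). AT2G10940 was at 798 ± 20.7 TPM (SD, n = 3) in wild type and at 0 in all 3 h3.3ko;HTR5 libraries, at least 3161-fold lower against a floor of 3 reads per library (limma adjusted p = 3.39e-14). Its neighbour AT2G10931 (4304762 to 4305887) went from 6.73 ± 0.85 TPM to 0 in all 3, at least 16.3-fold lower (limma adjusted p = 6.09e-06). AT2G10920 and AT2G10930, too low to be tested, had no reads in h3.3ko;HTR5 and only 1 and 15 in the 3 wild type libraries together, so the absence of AT2G10920 says nothing. DYL1, a dormancy-associated gene, fell from 55.6 ± 13.8 to 0.56 ± 0.15 TPM, and AT1G75945 from 26.6 ± 7.61 to 0.31 ± 0.54 TPM. The antimicrobial plant defensin genes PDF1.3, PDF1.2c and PDF1.2 fell by 3.76, 3.42 and 3.33 on the log2 scale, from wild type means of 20.9, 15 and 21.3 TPM. Wild type replicate 3 was lower than the other wild type libraries in all 3, at 4.87, 3.4 and 5.0 TPM. AT4G27654 (24.3 to 2.42 TPM) and MBP1, a myrosinase-binding protein gene (17.2 to 1.71 TPM), fell too. With limma's robust option the calls of PDF1.2c, PDF1.2 and AT4G27654 were lost (adjusted p = 0.0581, 0.0971 and 0.0723).

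The largest gain was AT5G45095 (chromosome 5, 18207363 to 18209052), which rose from 0.68 ± 0.06 to 93.1 ± 0.42 TPM (SD, n = 3; fold 136, limma adjusted p = 4.69e-11). AT2G05915, which overlaps AT2G05914 on chromosome 2 (2263816 to 2264265), rose from 0.94 ± 0.74 to 22.1 ± 1.97 TPM. HIS1-3, a linker histone H1 gene known to respond to drought, rose 4.05-fold, from 78.8 ± 15.7 to 319 ± 11.5 TPM (limma adjusted p = 6.09e-06). BXL1, a cell wall beta-xylosidase gene, rose from 100.1 ± 13.2 to 286 ± 29.6 TPM (limma adjusted p = 1.71e-05). AT4G40042 (18559097 to 18559570), on the opposite strand and upstream of HTR5 with 151 bp between them, rose from 18.17 ± 2.45 to 53.1 ± 7.64 TPM (limma adjusted p = 6.82e-05). Also among the 10 largest gains were ATMG00665, ATMG01370 and ATMG00690, which have mitochondrial identifiers. Mitochondrial genes as a whole held 0.0154% to 0.0305% of TPM in h3.3ko;HTR5 against 0.0104% to 0.0121% in wild type. ATMG00665 read 0, 0 and 14.5 TPM in wild type. Its call was lost when any library but wild type replicate 3 was left out (adjusted p = 0.0812 to 0.129), with no filter (adjusted p = 0.0755), with the robust option (adjusted p = 0.224) and with array weights (adjusted p = 0.0610). AT1G13540 rose from 1.98 to 6.57 TPM, a call lost without wild type replicate 2 (adjusted p = 0.0535) or h3.3ko;HTR5 replicate 3 (adjusted p = 0.0540). AT3G07522 was at 0 in wild type and at 1.202, 2.35 and 3.68 TPM in h3.3ko;HTR5. These are 1, 2 and 3 reads, at or below its floor of 3 reads, so no fold is given. Its call was lost with voom (adjusted p = 0.0717).

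**Figure D2:**
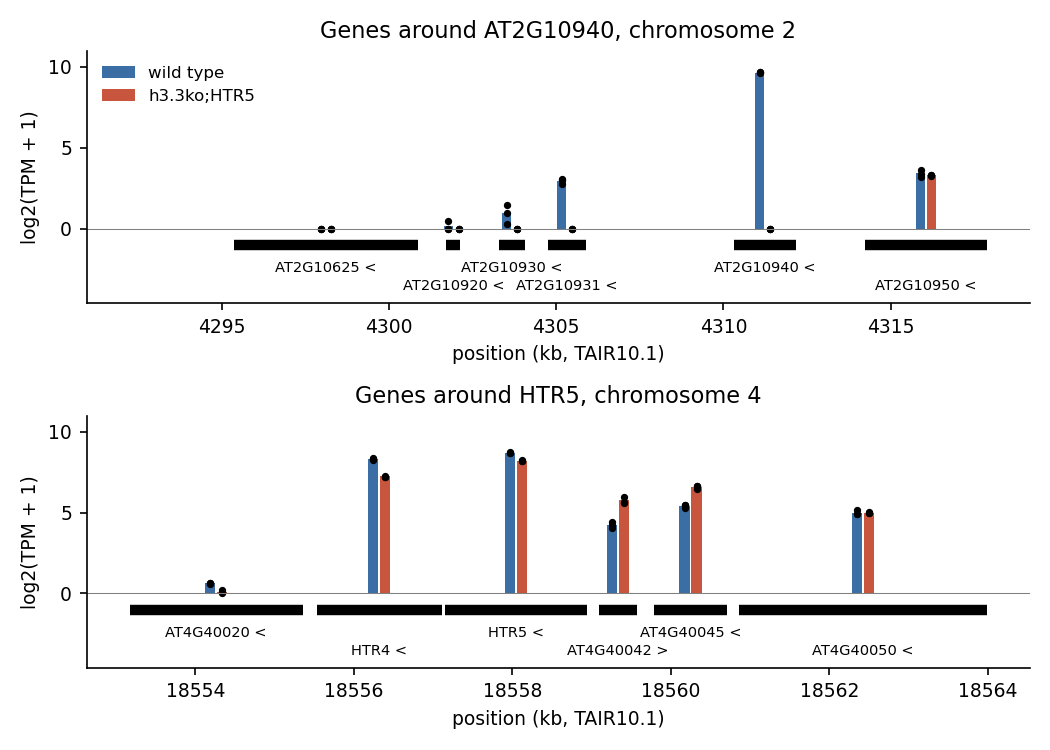
Levels as log2(TPM + 1) of the genes around AT2G10940 and around HTR5 along their chromosomes (kb, TAIR10.1), with wild type in blue, h3.3ko;HTR5 in red, bars at the log2 of the mean TPM + 1, points for single libraries, and black bars for the gene spans with the strand as an arrowhead. In h3.3ko;HTR5 the genes from AT2G10920 to AT2G10940 had no reads, and AT4G40042 and AT4G40045 beside HTR5 were higher than in wild type.

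Genes of flavonoid and anthocyanin synthesis fell together. All 14 tested members were lower in h3.3ko;HTR5. CHS (chalcone synthase, the entry enzyme of the pathway) fell from 782 ± 25.3 to 454 ± 50.2 TPM (SD, n = 3), and FLS1 (flavonol synthase) from 122 ± 1.39 to 69.6 ± 7.93 TPM. DFR (dihydroflavonol reductase) fell from 58.0 ± 1.94 to 29.9 ± 0.72 TPM, and TT19, needed for anthocyanin transport, from 27.2 ± 2.14 to 11.1 ± 1.70 TPM. The log2 fold changes of these 4 genes were -0.79, -0.81, -0.93 and -1.23 (limma adjusted p = 1.35e-04, 1.62e-04, 1.29e-05 and 1.63e-04). PAP1, the MYB regulator of anthocyanin genes, named after its values were seen, fell from 8.77 ± 2.91 to 2.07 ± 0.57 TPM. The count adjusted over the list alone was also 14 lower, and the median log2 fold change was -0.77. With 1 library left out the count was 12 without wild type replicate 2 or h3.3ko;HTR5 replicate 3 and 13 without wild type replicate 3 or h3.3ko;HTR5 replicate 1. TT8 and UGT79B1 lost their calls without wild type replicate 2, and TT8 without wild type replicate 3. The list was lower than other genes (camera adjusted p = 7.65e-13, and adjusted p = 0.364 with an estimated correlation).

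Cold-response genes were lower as well, 5 of 7 tested, with none higher. KIN1 and KIN2, cold-induced genes that lie side by side, fell from 36.9 ± 1.58 to 8.75 ± 3.09 TPM and from 222 ± 8.24 to 116 ± 15.4 TPM (limma adjusted p = 2.89e-04 and 1.32e-04). The transcription factor genes CBF2 and ZAT12 fell from 31.9 ± 11.9 to 7.11 ± 4.66 TPM and from 55.1 ± 24.0 to 11.1 ± 4.77 TPM (limma adjusted p = 0.00529 and 0.00160). The count was also 5 lower adjusted over the list alone. The list had a median log2 fold change of -1.45 (camera adjusted p = 3.80e-04, and adjusted p = 0.364 with an estimated correlation). In 4 of the 5 lower genes wild type replicate 1 was the highest library. The calls of CBF2 and ZAT12 were lost with limma's robust option (adjusted p = 0.0915 and 0.0526).

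Of 12 rapid stress and touch genes, 4 fell, 1 rose and 7 did not pass the test. CML38, a calmodulin-like gene, fell from 12.5 ± 5.4 to 1.53 ± 0.46 TPM. The transcription factor genes ERF5, ZAT10 and WRKY40 fell from 26.3 ± 8.27 to 8.92 ± 0.46, from 95.9 ± 39.2 to 30.5 ± 6.0 and from 19.4 ± 11 to 5.27 ± 0.10 TPM. In all 4 the highest wild type value was that of replicate 1. TCH4, a touch-induced cell wall enzyme gene named after its values were seen, rose from 213 ± 73.8 to 344 ± 6.38 TPM. Its call was lost when any library but wild type replicate 1 was left out (adjusted p = 0.0567 to 0.0791). Adjusted over the list alone, 2 were higher and 5 lower. The list did not pass the test against other genes (camera adjusted p = 0.150), except without wild type replicate 3 (adjusted p = 0.0133). With the robust option the calls of ZAT10, WRKY40 and TCH4 were lost (adjusted p = 0.0616, 0.0523 and 0.177), and TCH4 also lost its call with no filter on low values (adjusted p = 0.0563).

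Among jasmonate and ethylene defence genes, 8 of 13 fell and none rose (1 higher and 8 lower adjusted over the list alone, and 5 lower without a trend in the variance prior). Besides PDF1.2 they included JAZ1, a repressor of jasmonate signalling (41.2 ± 6.14 to 25.8 ± 1.44 TPM, limma adjusted p = 0.00236). AOC1, of jasmonate synthesis, fell from 64.6 ± 10.7 to 36.4 ± 5.37 TPM (limma adjusted p = 0.00322). The jasmonate-induced CORI3 fell from 8.9 ± 1.48 to 3.86 ± 0.32 TPM (limma adjusted p = 0.00118). In 5 of the 8 lower genes wild type replicate 1 was the highest library. The list was lower than other genes (camera adjusted p = 0.0428, and adjusted p = 0.824 with an estimated correlation). That call was lost without wild type replicate 2 (adjusted p = 0.0691), without h3.3ko;HTR5 replicate 1 (adjusted p = 0.197), with a pseudocount of 0.1 (adjusted p = 0.0597) and with array weights (adjusted p = 0.0638).

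Of 16 abscisic acid and drought genes 7 fell, 1 rose and 8 did not pass the test (8 lower and 2 higher adjusted over the list alone). ERD10 and COR47, dehydrin genes in tandem, fell from 168 ± 12.6 to 91.4 ± 4.26 TPM and from 246 ± 15.7 to 174 ± 7.1 TPM. RD29A fell from 31.2 ± 1.25 to 19.9 ± 0.93 TPM and RD22 from 337 ± 5.4 to 271 ± 8.7 TPM, all 4 with limma adjusted p from 3.88e-05 to 9.57e-04. RD29B, named after its values were seen, rose from 17.3 ± 4.67 to 26.5 ± 2.02 TPM. That call was lost without wild type replicate 2 or 3 or h3.3ko;HTR5 replicate 1 or 3 (adjusted p = 0.0711 to 0.0866). The list as a whole did not pass (camera adjusted p = 0.0724), but did on reads with voom (adjusted p = 0.0191) and with no filter on low values (adjusted p = 0.0461).

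Phosphate starvation genes showed 4 lower and 1 higher of 6 tested, over all genes and adjusted over the list alone. SPX1, a phosphate sensor gene, fell from 25.5 ± 7.39 to 12.2 ± 0.7 TPM, PAP17, an acid phosphatase gene, from 27.2 ± 4.36 to 17.39 ± 0.51 TPM, and the transporter gene PHT1;4 from 11.2 ± 1.505 to 6.87 ± 0.41 TPM. SQD2, of sulfolipid synthesis, rose from 63.4 ± 7.11 to 84.7 ± 5.07 TPM. The list test gave a camera adjusted p of 0.114, and 0.0416 without wild type replicate 3. Of 12 glucosinolate genes 6 fell and none rose, with the same counts adjusted over the list alone. Of the 12, 4 were lower after quantile normalization, median-of-ratios scaling or removal of the length trend, and 3 without a trend in the variance prior. The count was 3 without wild type replicate 2 and 4 without wild type replicate 3 or h3.3ko;HTR5 replicate 2 or 3. The 6 included CYP83A1 (244 ± 13.8 to 175 ± 2.67 TPM), CYP79F1 (70.8 ± 7.72 to 51.6 ± 1.82 TPM) and their regulator MYB28 (86.2 ± 1.28 to 64.3 ± 1.28 TPM). The glucosinolate list gave a camera adjusted p of 0.0601, which passed without wild type replicate 1 (adjusted p = 0.0283) and without h3.3ko;HTR5 replicate 2 (adjusted p = 0.0488), and reached 0.178 without wild type replicate 2.

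Nuclear photosynthesis genes were slightly higher with the TPM as deposited, 10 of 22 higher and none lower (15 and 0 adjusted over the list alone). The count depended on the setting and on single libraries. After quantile normalization 2 were higher and 2 lower, and 4 were higher after median-of-ratios scaling. The count was 3 with a replicate block, without a trend in the variance prior, with no filter on low values, and without wild type replicate 3 or h3.3ko;HTR5 replicate 1 or 3. Without wild type replicate 2 it was 6, with limma's robust option 14 and with voom 16. RBCS3B and RBCS2B, genes of the small Rubisco subunit, rose from 10516 ± 477 to 13467 ± 598 TPM and from 7806 ± 203 to 9404 ± 122 TPM. LHCB1.2, a light-harvesting gene, rose from 6524 ± 311 to 8095 ± 221 TPM. These 3 share 16.5%, 16.9% and 10.7% of their exon windows of 50 bases with other places in the genome, so the split of reads between gene copies is uncertain. Chloroplast-encoded genes held 0.316% of TPM in h3.3ko;HTR5 replicate 1 and 0.0991% to 0.117% in the other libraries. The list was higher than other genes (camera adjusted p = 1.42e-06, and adjusted p = 0.824 with an estimated correlation). After quantile normalization the list did not pass (adjusted p = 0.909), nor did RBCS3B (adjusted p = 0.126). That scaling makes the libraries equal at each rank. It can therefore remove a shared rise of very abundant transcripts, so these lost calls cannot decide. With 1 library left out the list stayed higher than other genes (camera adjusted p = 6.04e-08 to 5.49e-04).

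**Figure D3:**
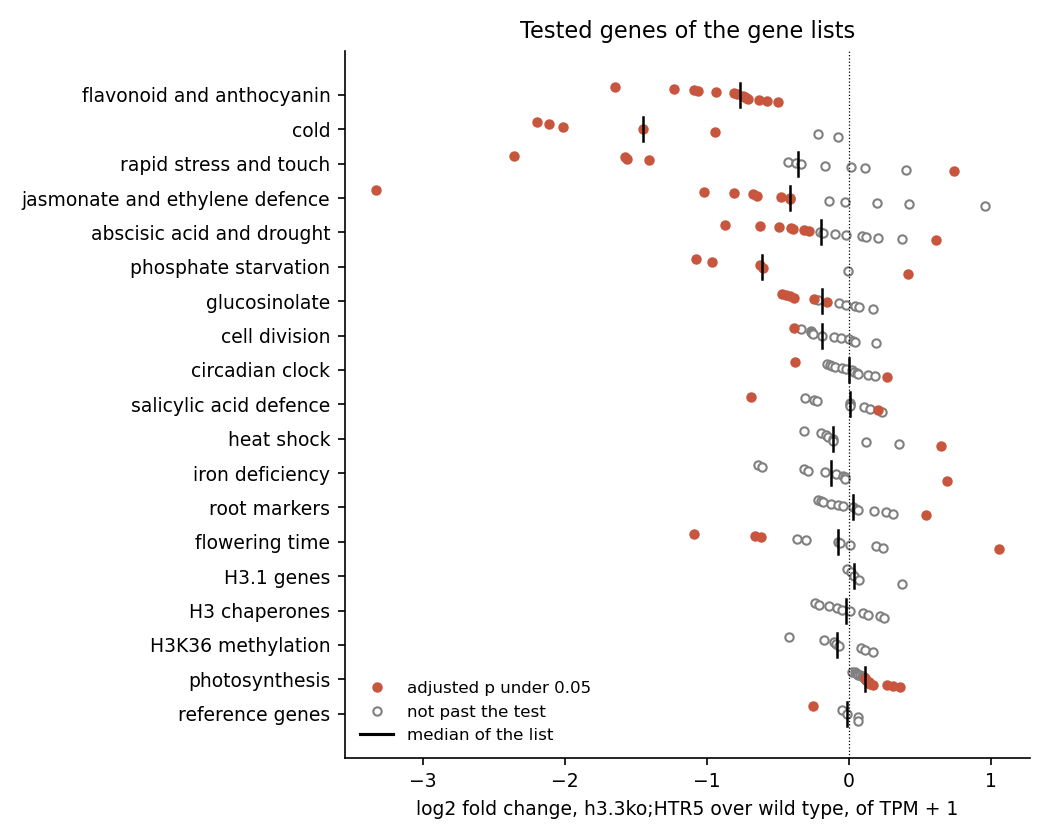
Log2 fold change of TPM + 1 (h3.3ko;HTR5 over wild type) of each tested gene in the gene lists, with filled points for a limma adjusted p under 0.05, open points for the others and a black line at each list's median. All 14 flavonoid and anthocyanin genes lie below 0, and the median of the 22 photosynthesis genes is 0.11 here and 0.0085 after quantile normalization.

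Transcript levels measure neither H3K36 methylation nor the H3.3 amino acid of the study's title. For genes linked to H3 and its K36 methylation, the test asks only whether their transcripts differed. None of 5 H3.1 genes, 10 H3 chaperone genes or 8 tested genes of the H3K36 methylation list passed it with limma on TPM. This held over all genes and adjusted over each list alone. The lists did not pass either (camera adjusted p = 0.387, 0.635 and 0.918). Among H3.1 genes, HTR2 stood at 195 ± 17.7 and 204 ± 11.4 TPM and HTR13 at 56.3 ± 3.7 and 57.8 ± 3.9 TPM in wild type and h3.3ko;HTR5. HIRA, a chaperone for H3.3, stood at 6.745 ± 0.66 and 8.19 ± 0.36 TPM (limma adjusted p = 0.147, and 0.0363 on reads with voom). UBN1, of the same chaperone complex, stood at 11.6 ± 1.04 and 13.6 ± 0.0652 TPM (limma adjusted p = 0.140, and 0.0420 with voom). MRG2, a reader of H3K36 methylation, stood at 7.18 ± 0.84 and 5.14 ± 1.06 TPM (limma adjusted p = 0.0900, and 0.0378 with voom). The chaperone list had a median of -0.02 and a mean of -0.0015, and the H3K36 list a median of -0.08 and a mean of -0.06. Camera placed both above other genes, and both medians turned positive after quantile normalization.

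Flowering time genes moved in both directions, with 3 lower and 1 higher of 11 tested (4 and 2 adjusted over the list alone; camera adjusted p = 0.558). The floral repressor FLC fell from 2.43 ± 0.10 to 1.17 ± 0.05 TPM and its relative MAF4 from 2.3 ± 0.28 to 1.15 ± 0.18 TPM. The flowering promoter AGL24 fell from 3.64 ± 0.61 to 1.18 ± 0.29 TPM. SPL3, a promoter of the adult phase, rose from 4.26 ± 0.73 to 9.89 ± 1.19 TPM. The limma adjusted p was 0.0177 for FLC, 0.0326 for MAF4, 0.00297 for AGL24 and 9.22e-04 for SPL3. The FLC call was lost without wild type replicate 2 or 3 or h3.3ko;HTR5 replicate 1 or 3 (adjusted p = 0.0511 to 0.0594). Its log2 fold change stayed between -0.68 and -0.64 whichever library was left out. The MAF4 call was lost without any library but h3.3ko;HTR5 replicate 2 (adjusted p = 0.0512 to 0.0991) after quantile normalization (adjusted p = 0.0632) and with a replicate block (adjusted p = 0.0631). Of the floral and meristem identity genes only STM was expressed enough to be tested, at 2.02 ± 0.34 and 2.18 ± 0.16 TPM (limma adjusted p = 0.792). Both tested genes of the list named silenced loci fell, also adjusted over the list alone, although ROS1 is expressed here. The DNA demethylase gene ROS1 fell from 23.2 ± 1.09 to 13.8 ± 0.52 TPM (limma adjusted p = 3.53e-04), and QQS from 3.9 ± 0.87 to 1.4 ± 0.14 TPM (limma adjusted p = 0.00340).

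Among 9 heat shock genes only HSP90.1, a cytosolic chaperone gene, changed, from 18.8 ± 1.28 to 30.03 ± 1.19 TPM (1 higher and 2 lower adjusted over the list alone). The list's median was -0.11, its mean 0.0074 and its camera direction down (adjusted p = 0.889). Of 11 salicylic acid defence genes, the regulator gene WRKY70 fell from 22.2 ± 4.39 to 13.3 ± 1.78 TPM and the immune receptor gene SNC1 rose from 73.9 ± 3.91 to 85.1 ± 2.88 TPM. Adjusted over the list alone the counts were the same, and the list had a median of 0.0047, a mean of -0.07 and camera direction up (adjusted p = 0.889). SNC1 shares 21.2% of its exon windows with other places in the genome, and its call was lost without any library but wild type replicate 1 (adjusted p = 0.0543 to 0.131). Its log2 fold change ran from 0.18 to 0.24 with 1 library left out. The SNC1 call was also lost with a replicate block (adjusted p = 0.0885) and without a trend in the variance prior (adjusted p = 0.124). Of 14 circadian clock genes PRR9 fell from 35.1 ± 2.27 to 26.8 ± 1.82 TPM and LNK2 rose from 445 ± 35.4 to 535 ± 14.3 TPM. The counts adjusted over the list alone were again the same, with a median of 0.00075, a mean of -0.01 and camera direction up (adjusted p = 0.889). PRR9 shares 41.1% of its exon windows, and the LNK2 call was lost without h3.3ko;HTR5 replicate 3 (adjusted p = 0.0542). In the iron deficiency list FRO2, the root iron reductase gene, rose from 15.1 ± 1.38 to 25 ± 3.1 TPM, 1 of 10 tested (1 adjusted over the list alone; camera adjusted p = 0.791). In the other direction, 2 members that did not pass here were lower in single settings. These were BHLH39 with voom (adjusted p = 0.0366) and without h3.3ko;HTR5 replicate 2 (adjusted p = 0.0106), and IMA2 without wild type replicate 3 (adjusted p = 0.0341). In the list of root markers IRT1, the root iron transporter gene, rose from 59.2 ± 6.56 to 87.8 ± 18.3 TPM, 1 of 13 tested (1 adjusted over the list alone; camera adjusted p = 0.545). The IRT1 call was lost without wild type replicate 1 or 2 or h3.3ko;HTR5 replicate 1 or 2 (adjusted p = 0.0764 to 0.0953), with no filter (adjusted p = 0.0583) and with the robust option (adjusted p = 0.102).

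Seed maturation genes were low in these seedlings and 2 of 4 tested were higher (3 adjusted over the list alone). The late embryogenesis gene EM6 rose from 6.85 ± 2.3 to 12.1 ± 1.46 TPM and the storage protein gene CRA1 from 0.65 ± 0.24 to 3.08 ± 1.74 TPM (limma adjusted p = 0.0238 and 0.0292). The list test (camera adjusted p = 0.0356, and adjusted p = 0.824 with an estimated correlation) was lost without wild type replicate 3 (adjusted p = 0.0559) and without h3.3ko;HTR5 replicate 1 (adjusted p = 0.0567) or 3 (adjusted p = 0.201). The EM6 call was lost without wild type replicate 2 or 3 or h3.3ko;HTR5 replicate 1 or 3 (adjusted p = 0.0532 to 0.0780) and with no filter (adjusted p = 0.0523). The CRA1 call was lost without any library but h3.3ko;HTR5 replicate 2 (adjusted p = 0.0531 to 0.112). Of 13 cell division genes the replication helicase gene MCM7 fell from 19.3 ± 2.42 to 14.4 ± 0.49 TPM, and 5 were lower adjusted over the list alone. The list gave a camera adjusted p of 0.222, or 0.0242 without wild type replicate 1. The MCM7 call was lost without any library but wild type replicate 1 (adjusted p = 0.0558 to 0.0769). Its log2 fold change ran from -0.46 to -0.29 with 1 library left out. TSO2, a ribonucleotide reductase gene, fell from 101.3 ± 9.59 to 78.7 ± 2.36 TPM as 1 of 6 DNA damage genes (1 adjusted over the list alone; camera adjusted p = 0.889). The sugar transporter gene SAG29 fell from 30.9 ± 4.38 to 15.3 ± 1.31 TPM as 1 of 4 senescence genes (2 adjusted over the list alone; camera adjusted p = 0.253). Of the 5 reference genes UBQ10 fell from 1465 ± 99.0 to 1228 ± 44.4 TPM (limma adjusted p = 0.0102, and 0.0882 without a trend in the variance prior), alone also when adjusted over the list alone. ACT2 had a log2 fold change of -0.05 that became 0.02 after quantile normalization. EF1A had one of -0.02 that became 0.03 after quantile normalization, 0.02 after median-of-ratios scaling and 0.01 with the length trend removed, and PP2AA3 and TIP41L had 0.07 and 0.06. None of these 4 passed the test, nor did the list (camera adjusted p = 0.988).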

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

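The tests on voom reads, on TPM with exon lengths and with the exon length trend removed were chosen only after the data were seen. The count of 2285 changed genes (703 higher, 1582 lower) became 1443 (414, 1029) without a trend in the variance prior, 194 (37, 157) with an added log2 fold change of at least 1, and 1289 to 2068 (354 to 753, 935 to 1341) with 1 library left out. Every other setting gave 1851 to 2899. Leaving out a library also lowers the power of the test, so a call lost that way need not mean that the estimate changed. The log2 fold change of a changed gene turned its sign in no setting, except for 3 genes under quantile normalization, counted whether called there or not. The replicate numbers showed no general pairing of the libraries (correlations of -0.04, 0.02 and -0.01 between those of the same number). Such correlations do not exclude a shared replicate order in some genes. A replicate block gave 1851 genes (547 higher, 1304 lower). The median log2 fold change ran from -0.07 in the fifth of genes with the shortest exons to -0.01 in the fifth with the longest.

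Of the genes chosen by rule, 2118 values over the alternatives stayed on their side of the test, 75 lost it and 13 gained it, and for lists these counts were 439, 21 and 11. Sign changes occurred 56 times, all in values not past the test, and the cause was not tested. The 13 gains were UBN1 and HIRA (higher) and MRG2, LNK1, PYK10, MCM2, MCM5, BHLH39 and SEN1 (lower) with voom, MCM2 with array weights, PYK10 and BHLH39 without h3.3ko;HTR5 replicate 2, and IMA2 without wild type replicate 3. The call of LHCB5 was lost with no filter, quantile normalization or a replicate block and without wild type replicate 3 or h3.3ko;HTR5 replicate 1 or 3, and that of SUR1 without wild type replicate 2. Among genes, array weights turned HTR9 to -0.0064 and OLEO2 to 0.044, and quantile normalization turned OLEO2 to 0.012, ACT2 to 0.016 and EF1A to 0.030. EF1A was 0.024 after median-of-ratios scaling and 0.013 with the length trend removed. With 1 library left out the log2 fold change ran from -0.0094 to 0.11 for HTR2, -0.010 to 0.086 for HTR13, -0.036 to 0.054 for HTR9, -0.013 to 0.15 for STM, -0.33 to 0.088 for OLEO2, -0.048 to 0.24 for XRI1, -0.037 to 0.0069 for EF1A, -0.045 to 0.090 for AT4G40050 and -0.21 to 0.0019 for AT2G10950.

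List medians changed sign as follows. The H3 chaperones were at 0.026 with a mean TPM of at least 5, 0.037 after quantile normalization, 0.015 after median-of-ratios scaling, 0.012 with the length trend removed and -0.049 to 0.030 with 1 library left out. H3K36 methylation was at 0.082 with a mean TPM of at least 5, 0.020 after quantile normalization and -0.097 to 0.0089 with 1 library left out. DNA damage was at 0.055 after quantile normalization, 0.025 with the length trend removed and -0.13 to 0.13 with 1 library left out, and reference genes at 0.030, 0.013 and -0.027 to 0.0069, and at 0.024 after median-of-ratios scaling. With no filter salicylic acid defence was at -0.025, circadian clock at -0.019 and root markers at -0.0042, and with a mean TPM of at least 5 circadian clock was at -0.050. With 1 library left out these 3 ran from -0.057 to 0.074, -0.061 to 0.057 and -0.019 to 0.067, H3.1 genes from -0.0094 to 0.086 and flowering time from -0.14 to 0.00059. Seed maturation also lost its call with a pseudocount of 0.1, quantile normalization, median-of-ratios scaling and the length trend removed (adjusted p = 0.0506, 0.0682, 0.0676 and 0.0590), glucosinolate passed with no filter and voom (adjusted p = 0.0461 and 0.00792), and senescence with no filter (adjusted p = 0.0481). With fry, which tests against no change and not against other genes, glucosinolate passed (adjusted p = 0.0255). The H3.3, flavonoid and anthocyanin, and cold lists kept their calls with fry (adjusted p = 8.02e-05, 0.00635 and 0.0107). Jasmonate and ethylene defence, photosynthesis and seed maturation did not (adjusted p = 0.0707, 0.0649 and 0.206). Without a trend in the variance prior the calls of ATMG00665, SNC1, LNK2, LHCB5, IRT1, EM6, CRA1, MCM7, SUR1, UBQ10, AT1G06760, AT5G59970, TCH4 and RD29B were lost (adjusted p = 0.0572 to 0.150). At 13792031 to 14498093 reads per library, genes under 1 TPM were not tested.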

Other observations

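The groups in this part and the tests on split libraries, wild type reads, adjacency, the next gene away, left-out libraries, handling and clock genes were chosen only after the result was seen, and the tests of repeated exon sequence were set before their values were known. Of 33 tested genes for the histones H1, H2A, H2B and H4, 15 rose in h3.3ko;HTR5, none fell and 18 did not pass the test (15 higher and 1 lower adjusted over these genes alone; camera adjusted p = 1.58e-06, and adjusted p = 0.169 with an estimated correlation). Of the genes for histone H4, 6 of 8 tested were higher and none lower (camera adjusted p = 2.72e-08 over 5 groupings, and adjusted p = 0.0948 with an estimated correlation). AT3G53730 rose from 125 ± 2.83 to 292 ± 14.9 TPM (SD, n = 3; limma adjusted p = 5.06e-07), and HIS4, AT5G59690 and AT1G07820 from 94.2 to 140 TPM, from 251 to 341 TPM and from 121 to 177 TPM. Of the 6, AT3G45930, AT1G07820, AT5G59690 and AT5G59970 share 25.7%, 19.4%, 8.48% and 6.94% of their exon windows with other places in the genome, and AT3G53730 and HIS4 share none. All 3 linker histone H1 genes rose, AT1G06760 by 0.18, AT2G30620 by 0.41 and HIS1-3 by 2.02 in log2 fold change (camera adjusted p = 5.51e-05, and adjusted p = 0.0688 with an estimated correlation). Of 9 tested H2B genes 4 rose (camera adjusted p = 0.0321, and adjusted p = 0.169 with an estimated correlation), and of 13 H2A genes HTA4 rose from 6.22 ± 0.46 to 13.97 ± 0.71 TPM and HTA7 from 89.0 ± 5.07 to 114 ± 3.47 TPM. The H2A group did not pass (camera adjusted p = 0.683), with a median of -0.10, a mean of 0.02 and camera direction up. The H4, H1, H2B and H2A counts were the same after quantile normalization and median-of-ratios scaling, but not in all settings. Of the H2B genes 1 was higher without wild type replicate 2, 2 without h3.3ko;HTR5 replicate 3 and 1 without a trend in the variance prior. Without that trend 5 H4 and 2 H1 genes were higher. Of the H2A genes 2 were lower without wild type replicate 1 and 2 without h3.3ko;HTR5 replicate 2.

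Among 176 families with the same product name and at least 10 tested genes, 3 passed with a preset correlation and none with an estimated one (adjusted p = 0.999 for each). The family named Histone superfamily protein, which includes HTR4, HTR5 and HTR8, had 9 of 29 higher and 3 lower. It did not pass (camera adjusted p = 0.156), unlike the histone groups above, which leave out H3 genes and were chosen after the values were seen. Disease resistance genes of the TIR-NBS-LRR class, which encode immune receptors, had 9 of 41 higher and none lower (camera adjusted p = 0.0167). One of them, AT1G63750, rose from 1.86 ± 0.55 to 3.62 ± 0.36 TPM (limma adjusted p = 0.0240), a call lost without wild type replicate 2 (adjusted p = 0.0706), h3.3ko;HTR5 replicate 2 (adjusted p = 0.0645) or h3.3ko;HTR5 replicate 3 (adjusted p = 0.0974). Genes annotated as Integrase-type DNA-binding proteins, which hold AP2/ERF transcription factors, had 10 of 47 lower and 3 higher (camera adjusted p = 0.0338), among them TINY2, which fell from 5.12 ± 0.69 to 1.46 ± 0.23 TPM (limma adjusted p = 5.60e-04). Genes annotated as cotton fiber protein had 4 of 13 lower and none higher (camera adjusted p = 0.0338). After quantile normalization the 3 families had 10 higher and 0 lower, 9 lower and 3 higher, and 4 lower and 0 higher. The TIR-NBS-LRR count fell when single libraries were left out. It was 2 higher without wild type replicate 2, h3.3ko;HTR5 replicate 2 or h3.3ko;HTR5 replicate 3, and 4 without wild type replicate 3. It was 3 without a trend in the variance prior and 5 with a replicate block. The Integrase-type genes had 6 lower without h3.3ko;HTR5 replicate 3. Of them 1 was higher without wild type replicate 2 or 3 or h3.3ko;HTR5 replicate 2 or 3, 2 without h3.3ko;HTR5 replicate 1, and none (7 lower) without the trend. Cotton fiber protein genes had 2 lower without wild type replicate 1.

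The 6 libraries can be split into groups of 3 in 10 ways, and only 1 of the 10, the split by genotype, gave as many as 2285 genes, while the highest of the other splits gave 0 (limma; 375 to 1014 genes at an unadjusted p under 0.05, against 5093). With 10 splits the share cannot fall under 0.05.

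The genes AT2G10920, AT2G10930, AT2G10931 and AT2G10940 lie in 10455 bp of chromosome 2 (4301708 to 4312162), and none had a read in h3.3ko;HTR5, while AT2G10950, the next gene, had a log2 fold change of -0.11 (limma adjusted p = 0.581). For AT2G10931 and AT2G10940, too few reads to see the genes is argued against by 144 and 27987 wild type reads. AT2G10930 had 15 and AT2G10920 only 1, so the 0 of AT2G10920 is uninformative and the run may begin after it. The run may also reach further on that side, since AT2G10625, the next gene there, had no reads in any library. For all 4 genes, reads placed on another copy are argued against by 0% of exon windows found elsewhere. The genes with a wild type mean of at least 1 TPM and no reads in h3.3ko;HTR5 number 5, and this pair of them sits side by side, which random draws of 5 genes matched in 8 of 10000 permutations (p = 0.0009). This adjacency prompted the test, so the p only restates how rare it is and does not weigh the explanations. A missing or rearranged segment in the h3.3ko;HTR5 line may account for the run, and a segment silenced as a whole predicts the same, so the cause stays open without DNA data.

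AT4G40042 and AT4G40045, the next genes upstream of HTR5 on chromosome 4, rose in h3.3ko;HTR5, the second (18559784 to 18560713) from 41.7 ± 2.90 to 95.5 ± 6.14 TPM (limma adjusted p = 1.09e-05). Reads of HTR5 placed on its neighbours are argued against by 0% of the neighbours' exon windows found elsewhere. The next gene away, AT4G40050, had a log2 fold change of 0.0068 (limma adjusted p = 0.970; -0.04 to 0.09 with 1 library left out). An extra copy of the segment upstream of HTR5 in the construct could raise just these genes, but the construct is not described in the sources used here, and a local effect of a changed HTR5 locus predicts the same, so the explanations cannot be told apart.

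In the cold, jasmonate and ethylene defence, rapid stress and touch, and flavonoid and anthocyanin lists, 31 genes were lower in h3.3ko;HTR5, and in 15 of them wild type replicate 1 was the highest library. These were 13 of the 17 cold, jasmonate and ethylene defence, and rapid stress and touch genes, and 2 of the 14 flavonoid and anthocyanin genes. A single stressed wild type library is argued against by the 93.5% of them that stayed lower without wild type replicate 1 (29 of 31; CBF1 and VSP2 were lost). Without wild type replicate 2, 26 were kept (CBF1, TT8, UGT79B1, VSP1 and VSP2 were lost), and without wild type replicate 3, 29 (TT8 and VSP1 were lost). Outside the flavonoid and anthocyanin list 15 of 17 (88.2%) stayed lower without wild type replicate 1. Their median log2 fold change went from -1.41 to -1.10, so that library adds to its size. Among the h3.3ko;HTR5 libraries, replicate 1 was the highest for ZAT12, CBF2, CML38 and ZAT10, and replicate 2 for ERF5, WRKY40, KIN1 and KIN2. A replicate order shared by both genotypes was thus seen in only some of these genes. For another time of day at harvest, the 14 clock genes had a median absolute log2 fold change of 0.108, with PRR9 lower and LNK2 higher. The 31 had 0.93, but they were picked for being lower, while all tested clock genes were used. That contrast therefore cannot decide on harvest time, and the values show only that the clock genes moved little as a set. Growth or handling that differed between the genotypes stays open, with 4 of 12 rapid stress and touch genes lower and TCH4 higher, because the labels do not say which plants were grown or harvested together. An effect of the genotype on these genes may explain the pattern too, as a hypothesis that these 6 libraries cannot separate from it.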
